A study of Mus musculus with 11 samples.

How the data were processed

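RNA of splenic T cells, isolated by negative magnetic bead selection, was labelled with biotin from 100 ng of total RNA and hybridised to one-colour Affymetrix mouse arrays, 1 array per sample. The labels call the arrays of a group biological replicates; nothing in the sources used here says that arrays with the same number share an animal. Per the submitters' processing notes, the images were handled with GCOS and the probe set values were computed with RMA in Partek; the versions of these tools are not given in the sources used here. The deposited log2 values of 45101 probe sets in 11 arrays were used as they stood. They ranged from 2.32 to 15.0, held 0 missing values, and had column medians between 5.84 and 5.89.

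Gene symbols were taken from the platform's annotation, matched by Entrez number to a mouse gene table of the assembly GRCm38.p6, which served only for names and neighbours. Of the 45101 probe sets 34958 carried 1 gene symbol, 932 carried several and 9211 carried none, and 34754 had an Entrez number found in the gene table; 0 symbols were changed by it. Each gene was represented by its probe set of highest mean over all arrays, which left 18194 genes, 9012 of them with more than 1 probe set. Among genes that passed, 81.0% of the other probe sets had the same direction in the naive genotype comparison, 92.3% in the activated one, 81.3% in wild-type activation and 82.5% in knockout activation. In the opposite direction, 261 of 8582 other probe sets passed over all probe sets in wild-type and 313 of 9163 in knockout activation, and 0 in either genotype comparison. Activation changes of named genes are those of the brightest probe set alone.

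Differences were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and moderated variances (prior degrees of freedom 5.46, residual degrees of freedom 7). The 6 comparisons were knockout against wild type in naive cells, in activated cells and on the mean of both, activated against naive in each genotype, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over the 18194 genes of a comparison, and an adjusted p under 0.05 is called past the threshold. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

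A total of 29 gene lists was fixed, 17 functional and 12 of cell type markers, with 441 members, of which 404 were measured and 37 had no name here. They were tested with camera in limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 29 lists, and again with the correlation estimated from the data. The version with an estimated correlation called 0 of the 29 lists in every comparison. It did not call even ribosome biogenesis in wild-type activation, where all 24 measured genes rose. Failing this version therefore cannot tell a shifted list from an unshifted one. Members were also counted after adjustment over the list alone. Direction of a list is that of its camera test.

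The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. Named were Crbn; the 10 largest rises and the 10 largest falls of each comparison among genes past the threshold whose arrays did not overlap between groups, the overlap condition not being applied to the interaction and the mean of both states; and, of each list, up to 4 members of largest absolute difference past the threshold or else the 1 of smallest p, given as not passing. Where fewer than 10 passed, all were eligible, and where 0 passed the 5 of smallest p were given as not passing. A gene named in 1 comparison may be given in another. Genes outside the rule are marked as chosen after their values were seen.

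The fit was tested on simulated data with the real group sizes and 200 changed genes among 18194. Of changes of 0.5, 1 and 2 log2 it recovered 71.6%, 98.5% and 100% in the naive genotype comparison, 68.7%, 95.5% and 100% in the activated one, 62.7%, 95.5% and 100% in wild-type activation, 74.6%, 94.0% and 100% in knockout activation, 29.9%, 85.1% and 98.5% in the interaction and 94.0%, 98.5% and 100% in the mean of both states. Between 2.82% and 5.38% of the simulated calls were false. A shift of 0.4 log2 in a list of 24 genes was called, and 0 of 20 unshifted lists were. The share of genes with the larger change in knockout cells was 48.3% when the simulated responses were equal and 79.9% when those of the knockout were 1.2 times as large. The simulated noise was independent between genes and between arrays. It held no shifts shared by many genes of an array, so these rates and shares need not carry over to the real arrays.

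The alternatives were counting all probe sets with 1 symbol, the mean of the probe sets of a gene, only the genes above the median of the mean level, a variance trend with a robust prior, no moderation, only the compared arrays, array quality weights, quantile normalization again, centring on the median, replicate number as a block, a block within genotype, leaving out each array, and a fold threshold. Leaving out both wild-type replicates numbered 1, and leaving out wild-type naive replicates 1 and 2, were chosen after seeing the data. Probe sets without a single gene symbol, 10092 in number once 51 control probe sets were set aside, were tested apart. The number of arrays limits the precision of every comparison, and the wild-type activated group had 2.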

Results

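Gene expression was measured on 11 one-colour Affymetrix arrays of T cells purified from the spleens of female mice aged 3 to 4 months. Cereblon, the product of Crbn, is the substrate receptor of a CUL4 ubiquitin ligase and the target of thalidomide and its relatives. C57BL6 wild-type animals were compared with crbn-/- (knockout) animals, and the cells were either naive or had been stimulated for 12 hours with plate-bound anti-CD3 and soluble anti-CD28, called activated here. The groups held 3 wild-type naive, 3 knockout naive, 2 wild-type activated and 3 knockout activated arrays. Values are log2 RMA expression levels, and 18194 genes were tested, each by its brightest probe set. Column medians lay between 5.84 and 5.89, and the number of arrays limits the precision. The median standard error of a genotype difference was 0.088 log2 in naive and 0.099 log2 in activated cells. Activation state carried 84.5% of the variance between arrays along the leading principal component. Pearson correlations across genes, which are not independent replicates, ranged from 0.994 to 0.997 within groups and from 0.956 to 0.970 between states.

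The deleted gene was examined as a check of the genotype. Crbn (probe set 1423095_s_at) stood at 10.12 ± 0.08 log2 (SD, n = 3) in wild-type naive cells and at 8.99 ± 0.08 (SD, n = 3) in knockout naive cells. In activated cells it stood at 9.59 ± 0.17 (SD, n = 2) and 8.68 ± 0.09 (SD, n = 3). Crbn was thus 2.19-fold lower in naive knockout cells (log2 difference -1.13, SE 0.085, limma adjusted p = 8.7e-05) and 1.87-fold lower in activated knockout cells (-0.90, SE 0.095, limma adjusted p = 0.0041), with every knockout array below every wild-type array of its state. The remaining signal was 45.6% of the wild-type level in naive and 53.4% in activated cells by this probe set. Probe set 1423094_at gave 47.0% and 53.3%, and probe set 1455734_at gave 59.1% and 68.0%; over all probe sets the last of these, in activated cells, had a limma adjusted p of 0.0695. Without wild-type activated replicate 1 the activated difference of Crbn was -0.78 with a limma adjusted p of 0.085. Crbn itself was lower in activated than in naive cells, by a log2 difference of -0.53 in wild-type and -0.30 in knockout cells (limma adjusted p = 4.9e-04 and 0.010). Which part of the gene was removed is not given in the sources used here.

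**Figure D1:**
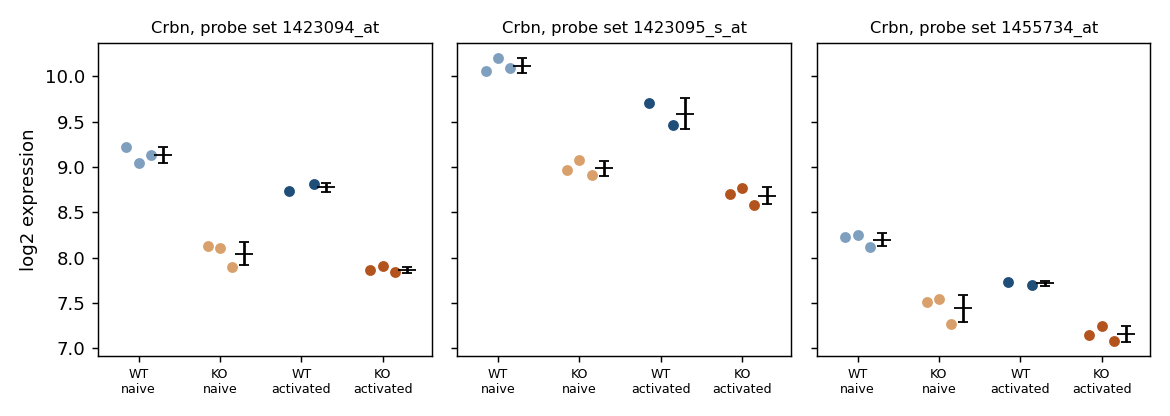
Log2 expression of the 3 Crbn probe sets in each array, with the group mean and SD beside the points (n = 3, 3, 2 and 3). Knockout arrays sit below wild-type arrays in both states, for probe set 1423095_s_at at 8.99 against 10.12 in naive cells.

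Activation of wild-type cells asked which genes differ between cells stimulated for 12 hours and naive cells. The labels list no group cultured without stimulation. Effects of the antigen-receptor and CD28 signals therefore cannot be told apart from those of culture or of a loss of other cells during it. The chemokine gene Ccl3 had the largest rise. It rose by 5.84 log2 (SE 0.27, 57.4-fold), from 6.24 ± 0.49 (SD, n = 3) to 12.08 ± 0.04 (SD, n = 2), and Xcl1 rose by 4.84 (SE 0.11), Ccl1 by 4.67 and Ccl4 by 4.03. Il2, the T cell growth factor, rose from 6.08 to 10.73, a difference of 4.65 (SE 0.22), and the granule protease gene Gzmb rose by 3.99. Spin4 (4.41), the microRNA-155 host gene Mir155hg (4.27), the transcription factor gene Irf4 (4.07) and the branched-chain aminotransferase gene Bcat1 (4.02) completed the 10 largest rises. Spin4 (3.91, 3.71 and 3.72) and, in 2 of 3 arrays, Mir155hg (4.79, 4.49 and 4.51) in naive cells, and A530021J07Rik (3.11 and 3.02) in activated cells, lay below the lowest lower quartile of any array (4.57), so signal above background was not shown there and the size and rank of their changes are uncertain. The largest falls were those of the phosphatase gene Dusp1 (-4.61, SE 0.10, from 12.89 to 8.28), Dtx1 (-4.22), A530021J07Rik (-4.06), Fosb (-3.88), Dzip1 (-3.83), Ampd3 (-3.80), Rasgrp2 (-3.77), the linker histone gene H1f2 (-3.75), Fos (-3.70) and the homing receptor gene Cxcr4 (-3.51). In all, 7475 of 18194 genes (41.1%) passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 3672 higher and 3803 lower after activation. Of these, 673 rose and 1021 fell at least 2-fold.

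The fixed gene groups described the wild-type response by function. All 24 measured ribosome biogenesis genes rose, by a median of 1.27 log2, among them Nolc1 (1.89), Nop16 (1.89), Tbl3 (1.80) and Rrp12 (1.63); the list had a camera adjusted p of 5.1e-16, and an adjusted p = 0.417 with an estimated correlation. Of 23 cytokine, chemokine and cytotoxic genes 18 rose and 2 fell (median 2.05, camera adjusted p = 3.5e-07; adjusted p = 0.417 with an estimated correlation). Of 29 T cell activation genes 20 rose and 4 fell (median 1.00, camera adjusted p = 5.5e-06; adjusted p = 0.421 with an estimated correlation), with rises of Nr4a3 (3.09) and Tnfrsf9 (2.98) and a fall of Junb (-3.04). Myc, a member of this list chosen after its values were seen, rose by 2.10. Glycolysis had 13 of 19 genes higher and 3 lower (median 0.62, camera adjusted p = 0.0012; adjusted p = 0.421 with an estimated correlation), led by Hk2 (2.87) and Pgam1 (1.51). Amino acid transport and glutamine metabolism had 12 of 19 higher and 2 lower (median 0.54, camera adjusted p = 0.0029; adjusted p = 0.417 with an estimated correlation), with Slc7a5 at 1.61, Cad at 1.52, Got1 at 1.43 and Ppat at 1.35. Oxidative phosphorylation had 17 of 24 higher and 0 lower in limma (median 0.32, camera adjusted p = 3.5e-04; adjusted p = 0.502 with an estimated correlation), with Cycs at 0.78 and Cyc1 at 0.62. The list of ATF4 targets and serine and folate enzymes had 11 of 17 higher and 3 lower (median 0.77, camera adjusted p = 0.0038; adjusted p = 0.450 with an estimated correlation), with Shmt2 at 1.76 and Psat1 at 1.49 but Ddit4 at -1.55. In the polyamine list 4 of 10 genes rose, among them the spermidine synthase gene Srm (2.16), and 3 fell; its median was -0.12 while its mean was 0.23 and the camera direction was up (camera adjusted p = 0.929).

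Of 22 naive and quiescence genes 14 fell and 2 rose (median -1.67, camera adjusted p = 3.5e-07; adjusted p = 0.417 with an estimated correlation), with Klf4 at -3.37, the egress receptor gene S1pr1 at -3.04, Klf2 at -2.94 and Txnip at -2.80. Of 18 type I interferon response genes 15 fell and 0 rose in limma (median -0.93, camera adjusted p = 5.5e-06; adjusted p = 0.450 with an estimated correlation), among them Mx1 (-2.09, with activated values of 4.44 and 4.59 near the quartile of 4.57), Ddx58 (-1.65) and Irf7 (-1.46). Of 17 effector and memory genes 10 fell and 3 rose (median -0.48, camera adjusted p = 0.017; adjusted p = 0.521 with an estimated correlation), with Ccl5 at -2.85 and Klrd1 at -1.79. Several T cell identity genes were lower after activation: 6 of 8 T cell markers fell and 1 rose (median -0.55, camera adjusted p = 0.0032; adjusted p = 0.421 with an estimated correlation), with Thy1 at -1.66. Both CD8 T cell markers fell (median -0.91, camera adjusted p = 0.042; adjusted p = 0.440 with an estimated correlation), with Cd8b1 at -1.24. Without wild-type naive replicate 3 or wild-type activated replicate 1 the CD8 list had a camera adjusted p of 0.052 or 0.091. Of the 3 CD4 T cell markers 2 fell, Cd4 at -1.07, with a camera adjusted p of 0.103 for the list. Regulatory T cell markers split into 3 lower and 1 higher of 7 (camera adjusted p = 0.106), with Itgae at -2.30. With the correlation estimated from the data, 0 of the 14 lists called by camera in wild-type activation passed, the lowest adjusted p with an estimated correlation being 0.417. Since ribosome biogenesis, with all 24 measured genes higher, was among those that failed, this version cannot decide which of the lists shifted.

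Other groups moved in both directions on wild-type activation. Of 26 cell cycle and replication genes 11 rose and 7 fell, with E2f2 at -2.39 and Mki67 at -2.29. The list's median was 0.06, its mean was -0.17 and its camera direction was up (camera adjusted p = 0.928). Over the 6 naive arrays this list's median followed that of the erythroid markers (r = 0.970). Its change on activation therefore cannot be told apart from a change in the mixture of cells. Of 15 heat shock and stress genes 5 rose, Hspd1 by 1.55, and 7 fell, Jun at -1.85 (camera adjusted p = 0.195). Inhibitory receptor genes had 6 of 10 higher and 3 lower, with Pdcd1 at 2.54, Lag3 at 1.87 and Cd274 at 1.64 but Ctla4 at -1.33 (camera adjusted p = 0.492). Calcium entry and ion channel genes had 4 of 13 higher and 6 lower, with Orai2 at -2.29 and Itpr3 at -1.83 (camera adjusted p = 0.119). In the list of the cereblon ligase and its reported substrates, Gspt1 rose by 1.19 while Prkaa1 (-1.31), Ikzf2 (-1.04) and Glul (-0.77) fell, with 3 of 17 higher and 7 lower (camera adjusted p = 0.423). Among 12 chromosome 6 neighbours of Crbn 4 rose and 2 fell (camera adjusted p = 0.519).

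Of the 8 marker lists of cells other than T cells, camera called the macrophage and B cell lists, both lower, in wild-type activation, and neither with an estimated correlation. Macrophage and monocyte markers had 9 of 15 lower (median -0.47, camera adjusted p = 4.9e-04; adjusted p = 0.421 with an estimated correlation), with Tyrobp at -1.52. B cell markers had 5 of 14 lower (median -0.40, camera adjusted p = 0.030; adjusted p = 0.533 with an estimated correlation), with Ighm at -1.56. Without wild-type activated replicate 1 this median was -0.22 (camera adjusted p = 0.15), and without wild-type naive replicate 3 it was -0.41 (camera adjusted p = 0.052). Jchain fell by 3.10 among the plasma cell markers, of which 2 of 6 fell and 1 rose (camera adjusted p = 0.406), and 2 of 8 neutrophil markers fell, Mpo at -2.28 (camera adjusted p = 0.423). In the dendritic cell list Ccl22 rose by 2.70 and Ccl17 by 0.65, with 2 of 8 higher and 3 lower (camera adjusted p = 0.721). NK cell markers had 3 of 5 lower and 1, Eomes at 1.26, higher (camera adjusted p = 0.155). Erythroid markers had 2 of 7 lower, Car1 at -3.19 and Car2 at -2.30 (camera adjusted p = 0.195), and platelet markers 1 of 6, Itgb3 at -1.28 (camera adjusted p = 0.519).

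Activation of knockout cells asked whether the same programme starts without cereblon. Ccl3 rose by 5.81 log2 (SE 0.24), from 6.34 ± 0.47 to 12.15 ± 0.20 (SD, n = 3 each), and Il2 rose by 5.47 (SE 0.20), from 5.66 ± 0.16 to 11.13 ± 0.39 (SD, n = 3 each). Spin4 rose by 4.99, Gzmb by 4.81, Mir155hg by 4.70, Xcl1 by 4.54, Bcat1 by 4.53, Ccl1 by 4.34, the retinoic acid binding protein gene Crabp2 by 4.29 and Irf4 by 4.24. Spin4 in naive cells (3.72, 3.68 and 3.21), Mir155hg in 2 of 3 naive arrays (4.61, 4.54 and 4.39), A530021J07Rik in activated cells (3.04 in each array) and Dzip1 in 1 activated array (4.43) lay below the same quartile of 4.57, which leaves the size and rank of their changes uncertain. The interleukin-2 receptor gene Il2ra rose by 3.37 and Myc, chosen after its values were seen, by 2.22. Dusp1 had the largest fall (-4.76), followed by Rasgrp2 (-4.46), H1f2 (-4.39), A530021J07Rik (-4.10), Fos (-4.08), Dtx1 (-4.01), S1pr1 (-3.99), Dzip1 (-3.89), the glucocorticoid-induced gene Tsc22d3 (-3.76) and Cxcr4 (-3.70). A total of 7851 genes (43.2%) passed in limma, 3770 higher and 4081 lower, with 1096 rising and 1067 falling at least 2-fold.

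By function, all 24 ribosome biogenesis genes rose in knockout cells (median 1.498, camera adjusted p = 5.3e-18, and an adjusted p = 0.362 with an estimated correlation), with Nop16 at 2.48, Nolc1 at 2.25 and Rrp12 at 2.10. Cytokine genes had 18 of 23 higher and 2 lower (median 1.95, camera adjusted p = 5.3e-07), T cell activation genes 21 of 29 higher and 5 lower (median 1.05, camera adjusted p = 6.1e-06) and glycolysis genes 14 of 19 higher and 4 lower (median 0.68, camera adjusted p = 3.2e-04), with Hk2 at 3.27, Pgam1 at 1.62 and Slc16a1 at 1.60. Each of these 3 lists had an adjusted p = 0.362 with an estimated correlation. Oxidative phosphorylation had 20 of 24 higher (median 0.37, camera adjusted p = 6.1e-06; adjusted p = 0.381 with an estimated correlation). Amino acid transport had 11 of 19 higher and 3 lower (median 0.36, camera adjusted p = 6.9e-04; adjusted p = 0.362 with an estimated correlation), with Slc7a5 at 2.02. The ATF4 list had 13 of 17 higher and 3 lower (median 0.74, camera adjusted p = 4.3e-04; adjusted p = 0.362 with an estimated correlation), with Asns at 2.51 and Psat1 at 2.00. Srm rose by 2.59, and the polyamine list again had a median, -0.09, of the other sign than its mean, 0.25. Quiescence genes had 15 of 22 lower and 2 higher (median -1.83, camera adjusted p = 5.3e-07; adjusted p = 0.362 with an estimated correlation), with Klf2 at -3.59 and Il7r at -3.00. Interferon response genes had 15 of 18 lower (median -1.02, camera adjusted p = 5.5e-05; adjusted p = 0.522 with an estimated correlation), with Ddx58 at -2.10. Cell cycle genes had 14 of 26 higher, Cdk6 by 1.78 and Gins1 by 1.77, and 3 lower, Mki67 at -1.67. Their median was 0.38 (camera adjusted p = 0.019, and an adjusted p = 0.717 with an estimated correlation). The erythroid signal of the naive arrays limits the reading of this call too. Heat shock genes had 7 of 15 higher and 6 lower, with a median of 0.12, a mean of -0.36 and an upward camera direction (camera adjusted p = 0.78). T cell markers had 6 of 8 lower (median -0.72, camera adjusted p = 0.0011), macrophage markers 11 of 15 lower (camera adjusted p = 3.2e-04) and B cell markers 7 of 14 lower (median -0.54, camera adjusted p = 0.022), the last with a camera adjusted p of 0.079 without knockout naive replicate 1 and 0.062 without knockout activated replicate 2. These had an adjusted p = 0.362, 0.362 and 0.599 with an estimated correlation, and of the 13 lists called by camera in knockout activation 0 passed with it.

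The responses of both genotypes were then set against each other. Of the genes past the threshold, 6240 changed in the same direction in both genotypes, 2919 up and 3321 down, where independent lists would share 761 and 853, and 15 changed in opposite directions. A further 1220 genes passed in wild-type cells only, 868 of them with the same sign in knockout cells, and 1596 passed in knockout cells only, 1331 with the same sign in wild-type cells. Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.935 and a Spearman correlation of 0.804. Among the 6240 shared genes the change was the larger in knockout cells for 71.4%, with a median absolute change of 0.762 log2 against 0.667. Without wild-type activated replicate 1 that share was 59.4%, and without wild-type activated replicate 2 it was 65.8%; the count of wild-type genes rising at least 2-fold, 673, was 926 or 525 without these arrays in turn. Per array the median response was 0.657 and 0.730 in wild-type and 0.766, 0.713 and 0.770 in knockout cells. The difference was 0.0563 with an exact two-sided permutation p of 0.3, where 0.1 is the smallest p these 5 arrays allow.

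**Figure D2:**
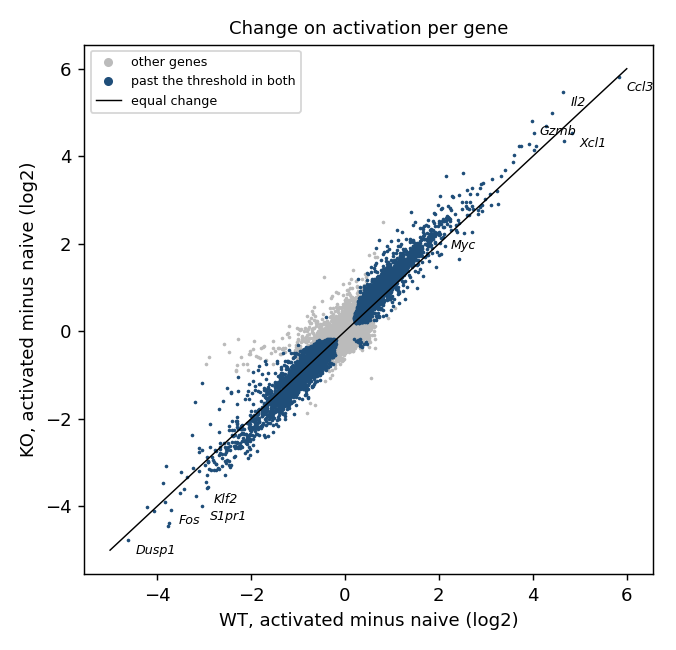
Log2 change on activation of each of 18194 genes in wild-type cells (horizontal axis) and knockout cells (vertical axis), with the line of equal change. The genes past the threshold in both genotypes, 6240 of them in the same direction, are dark; Ccl3 changed by 5.84 and 5.81, and Dusp1 by -4.61 and -4.76.

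The interaction of genotype and activation tested whether the response of any gene differed between knockout and wild-type cells. The genes with the smallest p were Adam24 (interaction -0.71), Hspa1a (1.32), the chemokine gene Cxcl3 (1.24), Afp (0.90) and Bambi-ps1 (-0.72), each with a limma adjusted p of 0.12. Il2 had an interaction of 0.82 (limma adjusted p = 0.29), S1pr1 of -0.95 (0.19), Gzmb of 0.82 (0.42), Wee1 of 1.04 (0.17) and Klf2 of -0.65 (0.28). limma called 0 genes, with 2515 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.122, and the fit without moderated variances called 1. Without wild-type naive replicate 3 the count was 4, and without wild-type activated replicate 2 it was 1, Cxcl3 (1.57, limma adjusted p = 0.0011), a fit in which the lone wild-type activated array left is assumed to vary like the other groups. All naive values of Cxcl3 (3.03 to 3.14) and its wild-type activated values (3.39 and 4.06) lay below the lowest lower quartile of any array (4.57), so the size of its interaction is uncertain. For gene groups, camera called 4 lists. The genotype difference of cell cycle genes was higher in activated than in naive cells by a median of 0.41 (camera adjusted p = 5.2e-09), of ribosome biogenesis genes by 0.22 (5.2e-08) and of heat shock genes by 0.21 (9.2e-04), and that of quiescence genes was lower (-0.13, 0.010). The 4 lists had an adjusted p = 0.904 or 0.927 with an estimated correlation. Erythroid markers, which the cell cycle list followed in naive arrays, had a median interaction of 0.84 (camera adjusted p = 0.180), and of 1.12 (0.038) without knockout naive replicate 1. The quiescence call was lost without knockout naive replicate 3 (camera adjusted p = 0.059), wild-type activated replicate 1 (0.31) or knockout activated replicate 1 (0.069). For ribosome biogenesis the median interaction was 0.12 without wild-type activated replicate 1 and 0.37 without wild-type activated replicate 2, and for cell cycle genes it was 0.27 without wild-type naive replicate 1.

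The naive comparison asked which genes differ between knockout and wild-type T cells at rest. In this and the other genotype comparisons, loss of cereblon cannot be told apart from other genetic differences between the mouse colonies. Besides Crbn, the largest falls were those of the endosomal GTPase gene Rab4a, from 8.83 ± 0.24 to 7.01 ± 0.20 (SD, n = 3 each; log2 difference -1.82, SE 0.13), Apol8, from 6.56 to 5.05 (-1.51, SE 0.14), and the mitochondrial transhydrogenase gene Nnt, from 9.30 to 8.15 (-1.15, SE 0.10). Their limma adjusted p were 8.7e-05, 2.9e-04 and 2.9e-04. The mitotic inhibitor kinase gene Wee1 (-0.91), the heat shock gene Hspa1a (-0.86), Slc35g1 (-0.81), Camk2b (-0.65), Rnf43 (-0.64) and Tmem181a (-0.60) were also lower. Mid1, a microtubule-associated ubiquitin ligase gene, had the largest rise, from 5.66 ± 0.40 to 7.75 ± 0.62 (SD, n = 3 each; 2.09, SE 0.33, limma adjusted p = 0.032), although its 2 other probe sets differed by 0.14 and 0.04. Rell1 rose by 1.15 (limma adjusted p = 3.3e-04), and by 1.35 in its other probe set. The NK receptor gene Klra8 (0.94), Cped1 (0.67), Neurl3 (0.65), App (0.64), the sodium channel gene Scn10a (0.54), Prss12 (0.52), the chemokine receptor gene Ccr6 (0.52) and Dpep3 (0.46) were also higher. The other probe set of Wee1 (-0.23), that of Cped1 (0.12) and all 3 others of App (0.28, -0.05 and -0.0002) did not pass; of the others of Nnt that at -1.01 passed and that at 0.17 did not. All 6 naive values of Scn10a lay below the lowest lower quartile of any array (4.57), so its signal was not shown to be above background. Every gene named in this paragraph as higher or lower had its 3 knockout arrays on one side of its 3 wild-type arrays, which 10% of unrelated genes would show by chance. This separation was a condition for naming the largest rises and falls, so it adds no evidence for them.

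A total of 27 genes passed in limma in naive cells, 14 higher and 13 lower in knockout cells, and 6 of them differed at least 2-fold; 2642 genes had an unadjusted p under 0.05. The count was 11 (3 higher and 8 lower) without wild-type naive replicate 1, 12 (4 higher and 8 lower) without wild-type naive replicate 2, 341 (91 higher and 250 lower) without wild-type naive replicate 3, 74 (25 higher and 49 lower) without knockout naive replicate 1 and 10 (3 higher and 7 lower) without either knockout naive replicate 2 or 3. Rab4a, Apol8, Nnt, Crbn, Slc35g1, Rnf43, Rell1 and Neurl3 passed in each of these fits, while Mid1 had a limma adjusted p of 0.052, 0.13, 0.12 and 0.12 without wild-type naive replicate 1, wild-type naive replicate 2, knockout naive replicate 2 and knockout naive replicate 3. Klra8, Wee1, Hspa1a, Cped1, App, Scn10a, Prss12, Ccr6, Dpep3, Camk2b and Tmem181a also lost their call without at least 1 of these arrays.

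Of the 29 fixed lists camera called 8 in naive cells, 0 of them with an estimated correlation, and Crbn, Hspa1a and Klra8 were the only members past the threshold in limma. Cell cycle genes had a median difference of -0.40 (camera adjusted p = 2.1e-12; adjusted p = 0.550 with an estimated correlation), with 16 of 26 lower when adjusted over the list alone and 0 over all genes in limma. Cdk6 differed by -0.59 (limma adjusted p = 0.099) and Mki67 by -0.86 (0.17). Per array the list's median was 0.46, 0.12 and -0.01 in wild-type cells and 0.02, -0.25 and -0.35 in knockout cells. The erythroid markers moved alongside, at 1.11, 0.65 and -0.17 in wild-type and 0.04, -0.54 and -1.07 in knockout arrays, with a median difference of -1.06 (camera adjusted p = 0.060, with 4 of 7 lower when adjusted over the list alone). The list passed without wild-type naive replicate 2 (camera adjusted p = 0.045), wild-type naive replicate 3 (0.011) or knockout naive replicate 1 (0.0088). Leaving out wild-type naive replicate 1 brought the cell cycle median to -0.25, still called. Ribosome biogenesis genes had a median of -0.13 (camera adjusted p = 2.3e-06; 1 lower when adjusted over the list alone) and heat shock genes of -0.16 (1.5e-04; 7 lower when adjusted over the list alone). Glycolysis (-0.10, camera adjusted p = 0.023; 3 lower when adjusted over the list alone), oxidative phosphorylation (-0.07, 0.0081) and quiescence genes (0.08, 0.022) differed little. Their calls were lost without wild-type naive replicate 1 (camera adjusted p = 0.092, 0.15 and 0.084), that of glycolysis also without knockout naive replicate 1 (0.064) and that of quiescence without knockout naive replicate 3 (0.083).

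B cell markers were higher in naive knockout cells (median 0.43, camera adjusted p = 1.5e-04; 0 of 14 passed when adjusted over the list alone), with Cd79b at 0.47, Cd79a at 0.42 and H2-Aa at 0.57. Knockout naive replicate 1 had the highest B cell median, 0.66, and without it the difference was 0.19 (camera adjusted p = 0.10). NK cell markers were higher as well (median 0.44, camera adjusted p = 0.026, with 3 of 5 higher when adjusted over the list alone), Klra8 among them, but not without wild-type naive replicate 3 (camera adjusted p = 0.10) or knockout naive replicate 1 (0.18). The NK markers did not move together. Klra7 was lower, at 7.61 in wild-type and 7.14 in knockout naive cells, and Eomes stood at 9.14 and 9.18. Tyrobp, at 7.85 and 8.36, is also a member of the macrophage list. Neutrophil markers had a median of 0.40 (camera adjusted p = 0.147), and 0.57 (0.0024) without knockout naive replicate 3. Their median per array was 0.90, -0.07 and -0.29 in knockout and -0.27, -0.34 and 0.00 in wild-type cells, so the difference rested mainly on knockout naive replicate 1. The naive difference of interferon response genes, 0.02, was 0.18 without wild-type naive replicate 1 (camera adjusted p = 1.6e-04). This list's median per array was 0.33, -0.26 and -0.13 in wild-type and -0.03, 0.10 and -0.06 in knockout cells. The wild-type arrays thus lay on both sides of the knockout arrays. Lists tied to the study's subject differed little: T cell activation genes by 0.06 (camera adjusted p = 0.475), cytokine genes by 0.05 (0.433), amino acid transport by -0.10 (0.070), polyamine genes by -0.01 (0.433), and T cell markers by 0.06 (0.433). Myc, chosen after its values were seen, differed by 0.02. In the cereblon ligase list Crbn alone passed. Among the 12 chromosome 6 neighbours 0 genes passed in limma; Trnt1 came closest (-0.44, limma adjusted p = 0.069). With an estimated correlation 0 of the 8 lists called by camera passed, with an adjusted p of 0.550 for cell cycle, ribosome biogenesis, heat shock, glycolysis, B cell and NK cell genes and 0.584 for oxidative phosphorylation and quiescence genes.

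**Figure D3:**
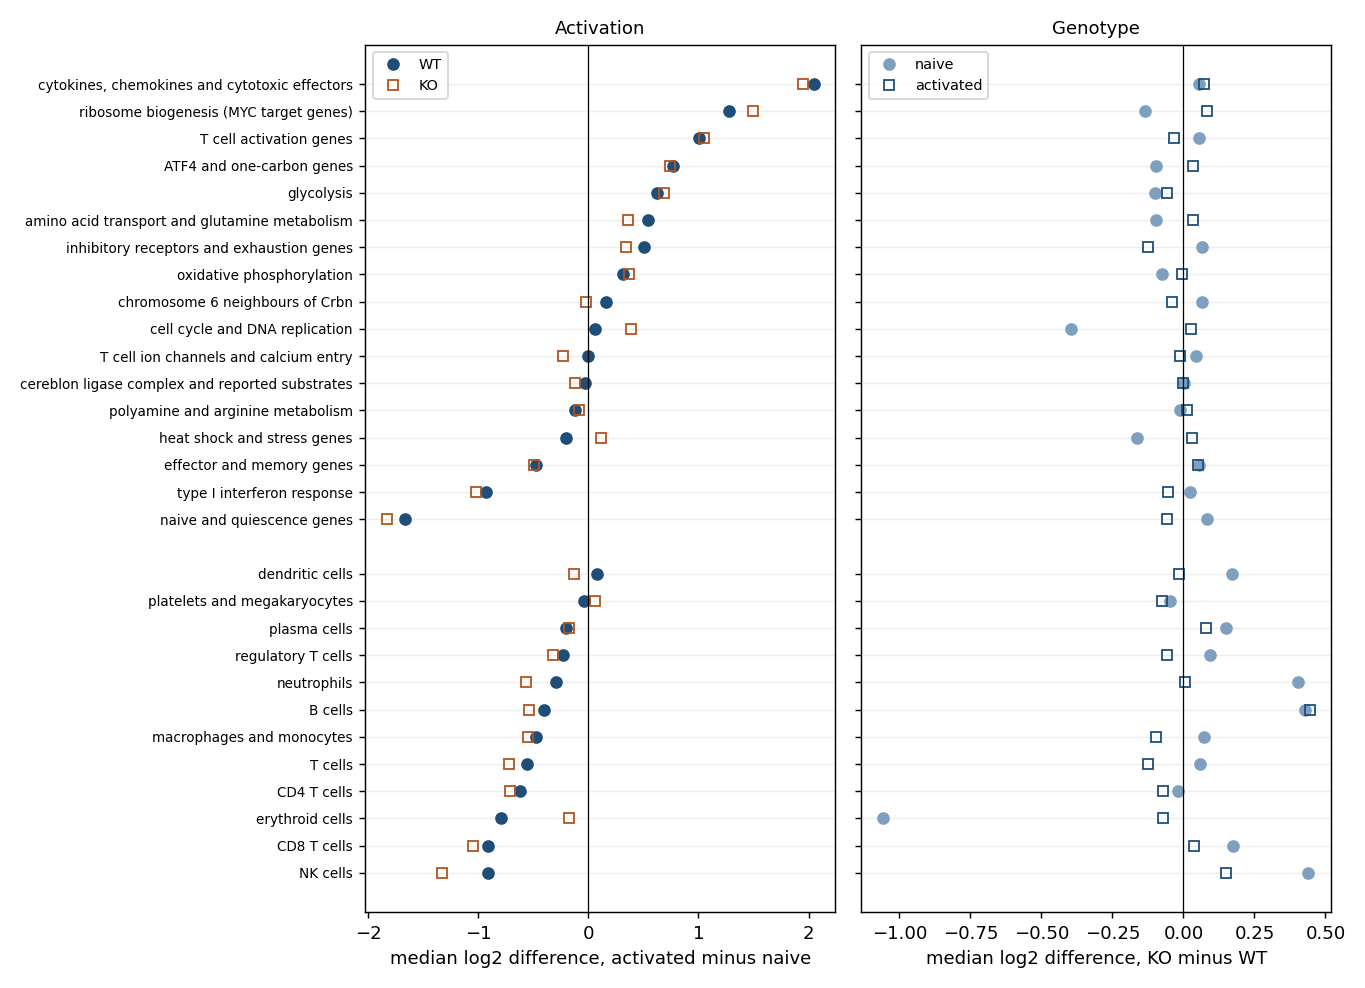
Median log2 difference of each of the 29 fixed gene lists, on activation in wild-type and knockout cells (left) and between knockout and wild-type cells in each state (right); the lower block holds cell type markers. Ribosome biogenesis genes rose by 1.27 and 1.498 on activation, and erythroid markers differed by -1.06 between genotypes in naive cells.

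The activated comparison asked which genes differ between knockout and wild-type cells after stimulation. Rab4a was again lower, at 7.54 ± 0.03 (SD, n = 2) in wild-type and 6.02 ± 0.18 (SD, n = 3) in knockout cells (-1.51, SE 0.15, limma adjusted p = 0.0032), and Mid1 again higher (2.59, limma adjusted p = 0.023). The other probe sets of Mid1 differed by 0.04 and 0.18 and did not pass, so this rise rests on its brightest probe set alone. Tmem267 was higher by 1.76 (limma adjusted p = 0.018), at 6.13 and 7.22 in the wild-type and 8.15, 8.65 and 8.50 in the knockout arrays. Both chemokine genes that passed were higher, Cxcl3 by 1.27 (limma adjusted p = 0.0048), from 3.73 to 4.99, and Ccl17 by 0.82 (0.018), from 6.24 to 7.06. The circadian transcription factor gene Npas2 was higher by 1.08, Afp by 0.94, the neurotensin gene Nts by 0.86 and Arhgap5 by 0.60, and Bambi-ps1 was lower (-0.65). The values of Cxcl3 (3.39 and 4.06) and Nts (4.28 and 4.40) in both wild-type activated arrays lay below the lowest lower quartile of any array (4.57), so signal above background was not shown there and the size of these differences is uncertain. For Npas2 the other probe set, at 0.01, did not pass, nor did the 3 others of Arhgap5 (0.36, 0.40 and 0.01), and of the 4 other probe sets of Afp those at 0.88 and 0.78 passed. Nnt differed by -0.70 (limma adjusted p = 0.065), while of its other probe sets that at -0.76 passed over all probe sets (0.016) and that at -0.09 did not. The other probe set of Rab4a differed by -1.25 (limma adjusted p = 0.056 over all probe sets). Apol8 differed by -0.29 (limma adjusted p = 0.77), but its 5 activated values (3.74 to 4.35) lay below the same quartile of 4.57, so a difference there could not be measured. A total of 11 genes passed in limma, 8 higher and 3 lower, 5 of them at least 2-fold, with 1256 at an unadjusted p under 0.05. The count was 1 without wild-type activated replicate 1, which left that group with 1 array assumed to vary like the others, and 28 (6 higher and 22 lower) without knockout activated replicate 2 and 4 (2 higher and 2 lower) without knockout activated replicate 3. Cxcl3, with the limit just given, was the 1 gene that passed in all of the fits that left out 1 array. Without wild-type activated replicate 1 Rab4a differed by -1.53 (limma adjusted p = 0.085), Afp by 0.89 (0.11), Tmem267 by 1.22 (0.14) and Mid1 by 2.39 (0.50). Without wild-type activated replicate 2 Mid1 (limma adjusted p = 0.12), Ccl17 (0.13), Nts (0.079) and Bambi-ps1 (0.060) lost their calls. Without knockout activated replicate 3 only Crbn, Rab4a, Cxcl3 and Afp kept theirs; Mid1 (0.054) and Arhgap5 (0.067) lost theirs in limma without knockout activated replicate 2, and Arhgap5 (0.064) and Bambi-ps1 (0.051) without knockout activated replicate 1.

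Between the activated genotypes the cytokine genes Il2 (0.40, limma adjusted p = 0.78) and Csf2 (0.54, 0.49), Gzmb (0.48, 0.84), Ctla4 (-0.46, 0.37), S1pr1 (-0.74, 0.21) and Cd44 (0.38, 0.40) did not pass. Csf2 passed without wild-type activated replicate 2 (0.94, 0.018) and S1pr1 without knockout activated replicate 2 (-0.89, 0.034). Myc, chosen after its values were seen, differed by 0.14. B cell markers were higher in knockout cells (median 0.45, camera adjusted p = 8.8e-04; adjusted p = 0.894 with an estimated correlation), at -0.58 and 0.00 in wild-type and 0.42, -0.01 and 0.04 in knockout arrays. The difference was 0.12 (camera adjusted p = 0.21) without wild-type activated replicate 1 and 0.30 (0.15) without knockout activated replicate 1. Ribosome biogenesis genes were higher by a median of 0.08 (camera adjusted p = 8.8e-04; adjusted p = 0.894 with an estimated correlation), but lower (-0.05, 0.85) without wild-type activated replicate 1. NK cell markers were higher by 0.15 (camera adjusted p = 0.019; adjusted p = 0.894 with an estimated correlation), a call lost without either wild-type array (0.21 and 0.11) or knockout activated replicate 1 (0.19). Each of these lists had 0 members past the threshold when adjusted over the list alone. Cytokine genes differed by 0.07 (camera adjusted p = 0.061), and by 0.16 (0.013) without wild-type activated replicate 2 or 0.20 (1.5e-05) without knockout activated replicate 2. T cell activation genes differed by -0.03, with a mean of 0.02 and an upward camera direction (camera adjusted p = 0.182), glycolysis genes by -0.06 (0.743), cell cycle genes by 0.03 (0.203) and chromosome 6 neighbours by -0.04 (0.740). The T cell activation median per array was -0.14 and 0.08 in wild-type and 0.03, -0.13 and 0.15 in knockout cells, so its difference depends on the arrays kept. The erythroid markers had a median of -0.07, a mean of -0.12 and an upward camera direction (camera adjusted p = 0.934).

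The mean of the genotype differences over both states asked which genes differ between knockout and wild-type cells whatever the state. Its fit counted all arrays as independent, although the labels do not say whether same-numbered arrays share an animal. Rab4a (-1.67, SE 0.10, limma adjusted p = 9.9e-06), Crbn (-1.02, 1.0e-05), Nnt (-0.93, 2.1e-04), Apol8 (-0.90), Slc35g1 (-0.50), the regulatory T cell gene Gpr83 (-0.48), Tmem181a (-0.45) and Rnf43 (-0.40) were lower. Mid1 (2.34, limma adjusted p = 0.0017), Erdr1 (1.61, 0.037), Tmem267 (1.48, 0.0021), Gprin3 (0.92), Rell1 (0.75), Cxcl3 (0.65), App (0.54), Tent5a (0.50), Afp (0.49) and Arhgap5 (0.45) were higher, with 5830416I19Rik (0.30). All activated values of Apol8 (3.74 to 4.35) and all naive values of Cxcl3 (3.03 to 3.14) lay below the lowest lower quartile of any array (4.57), so the call of Apol8 rests on naive cells and that of Cxcl3 on activated cells. Erdr1 ranged from 10.34 to 10.92 in wild-type and from 11.26 to 12.74 in knockout arrays, with a pooled call that was lost without any of 9 arrays. These were the 19 genes past the threshold in limma, 11 higher and 8 lower, with 1298 at an unadjusted p under 0.05, and 9 passed without wild-type activated replicate 1. Crbn, Rab4a, Nnt, Slc35g1, Mid1, Tmem267 and Rell1 passed in every fit that left out 1 array. The other probe set of Gprin3 (0.36, with -0.16 in naive and 0.88 in activated cells) passed over all probe sets and that of Erdr1 (0.31) did not. Nor did the others of Mid1 (0.09 and 0.11), App (0.20, 0.02 and -0.01) or Arhgap5 (0.45, 0.13 and 0.08). By the brightest probe set of each gene, Crbn, Mid1 and Rab4a passed in each state separately, 3 genes where independent lists would share 0.0163. Another probe set of Nnt (-1.01 in naive and -0.76 in activated cells), of Rell1 (1.35 and 0.77) and of Gpr83 (-0.63 and -0.64) also passed in each state over all probe sets. Of the 27 naive calls 17 had the same sign in activated cells, and of the 11 activated calls 8 had the same sign in naive cells. Among lists, B cell markers were higher by a median of 0.45 (camera adjusted p = 1.2e-08, 8 of 14 when adjusted over the list alone, adjusted p = 0.380 with an estimated correlation), and NK cell markers by 0.29 (2.0e-04, adjusted p = 0.340 with an estimated correlation). Wild-type activated replicate 1 had the lowest B cell median of its state, -0.58, and knockout naive replicate 1 the highest of its own, 0.66. The size of the B cell difference therefore rests in part on these arrays. Of the 10 lists called by camera on the mean of both states, 0 passed with an estimated correlation, and the calls of 6 lists held in only 5 to 9 of the 11 fits that left out 1 array. Cytokine genes (0.05, camera adjusted p = 0.022; adjusted p = 0.644 with an estimated correlation) were not called without wild-type naive replicate 2 (0.096), knockout naive replicate 1 (0.23), knockout activated replicate 3 (0.30) or wild-type activated replicate 1 (0.55), where the median was -0.01. Glycolysis genes (-0.07, camera adjusted p = 0.022; adjusted p = 0.644 with an estimated correlation) were not called without wild-type naive replicate 1 (0.087), wild-type activated replicate 2 (0.53) or knockout activated replicate 2 (0.054). Nor were heat shock genes (-0.07, 0.022; adjusted p = 0.534 with an estimated correlation) without wild-type naive replicate 1 (0.059) or wild-type activated replicate 2 (0.33). Platelet markers (-0.09, camera adjusted p = 0.027; adjusted p = 0.340 with an estimated correlation) were not called without wild-type naive replicate 3 (0.061), knockout naive replicate 1 (0.076) or 2 (0.052), or wild-type activated replicate 1 (0.12) or 2 (0.075). Effector and memory genes (0.07, camera adjusted p = 0.031; adjusted p = 0.644 with an estimated correlation) lost their call without wild-type naive replicate 2 (0.12), knockout naive replicate 1 (0.58), wild-type activated replicate 1 (0.12) or 2 (0.084), or knockout activated replicate 1 (0.057) or 2 (0.085). Plasma cell markers (0.11, camera adjusted p = 0.031; adjusted p = 0.534 with an estimated correlation) lost theirs without wild-type naive replicate 3 (0.16), knockout naive replicate 1 (0.13) or 3 (0.056), wild-type activated replicate 1 (0.12) or 2 (0.075), or knockout activated replicate 1 (0.071). Dendritic cell markers were higher by 0.10 (camera adjusted p = 0.0026, adjusted p = 0.223 with an estimated correlation), but not without wild-type activated replicate 2 (0.084), and cell cycle genes were lower (-0.20, 1.9e-06, adjusted p = 0.644 with an estimated correlation). Wild-type naive replicate 1 had the highest cell cycle median of the naive arrays, 0.46, so part of the cell cycle difference may rest on it. The erythroid markers differed by -0.64 alongside (camera adjusted p = 0.130), and passed without wild-type naive replicate 3 (-0.81, 0.017) or knockout naive replicate 1 (-0.77, 0.027).

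**Figure D4:**
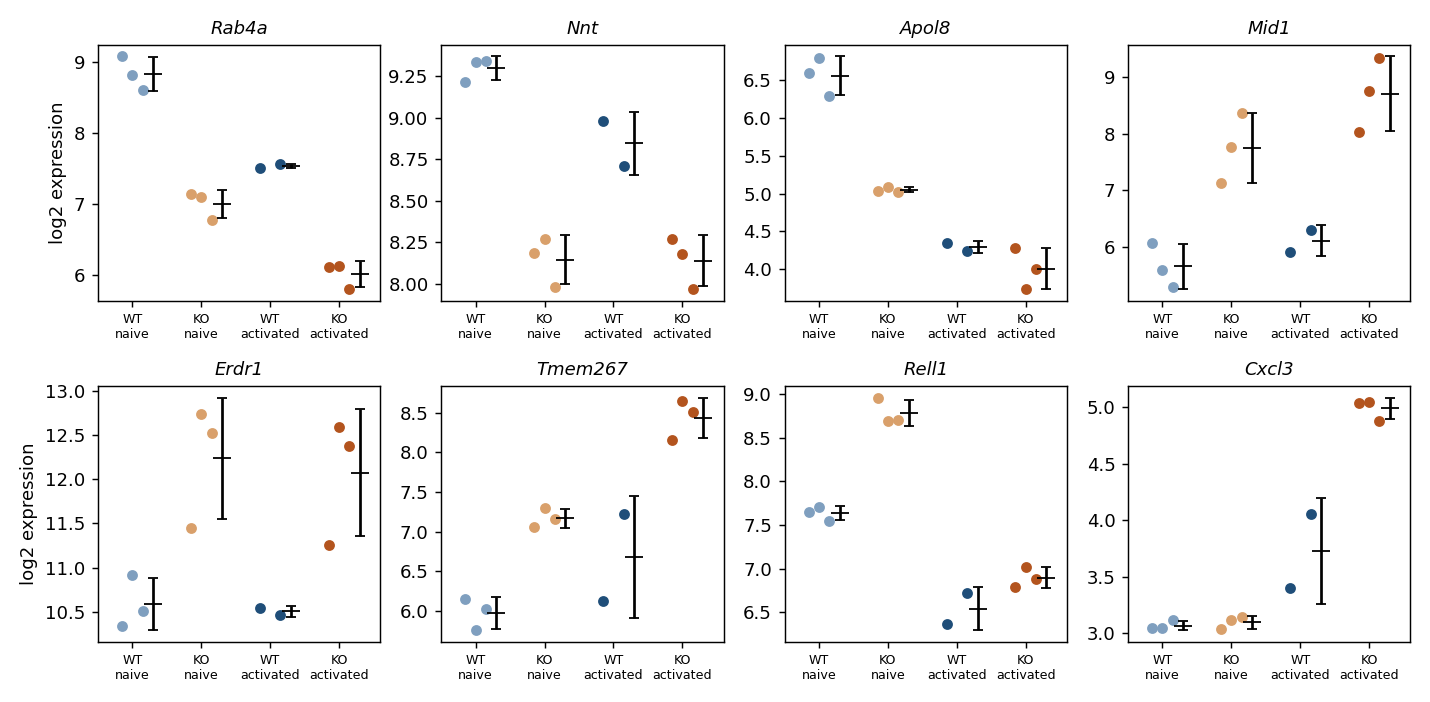
Log2 expression per array of 8 genes named in the genotype comparisons, with the group mean and SD beside the points (n = 3, 3, 2 and 3; each panel has its own scale). By the brightest probe set of each gene, Rab4a was lower in knockout cells by -1.82 and -1.51, and Mid1 higher by 2.09 and 2.59, in naive and activated cells.

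Arrays of a group did not all lie together. Along the component that held 6.28% of the variance wild-type naive replicate 1 stood at 27.7 and knockout naive replicate 3 at -20.1, the same arrays that had the highest and lowest erythroid and cell cycle medians. In wild-type naive replicate 1 the erythroid genes Car2 and Slc4a1 reached 11.8 and 10.02, against 8.14 and 6.67 in knockout naive replicate 3, and Mki67 reached 10.7 against 9.15. Along the component that held 2.00% of the variance wild-type activated replicate 1 stood at -18.0, apart from every other array, and its ribosome biogenesis median was -0.19 against 0.07 in the other wild-type activated array. The 3' minus 5' signal of the actin control probe sets, a measure of RNA integrity, was 0.43 ± 0.0093 in wild-type naive, 0.41 ± 0.032 in knockout naive and 0.55 ± 0.015 in knockout activated cells (SD, n = 3 each), and 0.49 ± 0.050 in wild-type activated cells (SD, n = 2). That of the Gapdh control probe sets was 0.452 in knockout naive replicate 3, the array with the lowest cell cycle and erythroid medians, against 0.267 and 0.268 in the other knockout naive arrays and 0.354 ± 0.0067 in wild-type naive cells (SD, n = 3).

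**Figure D5:**
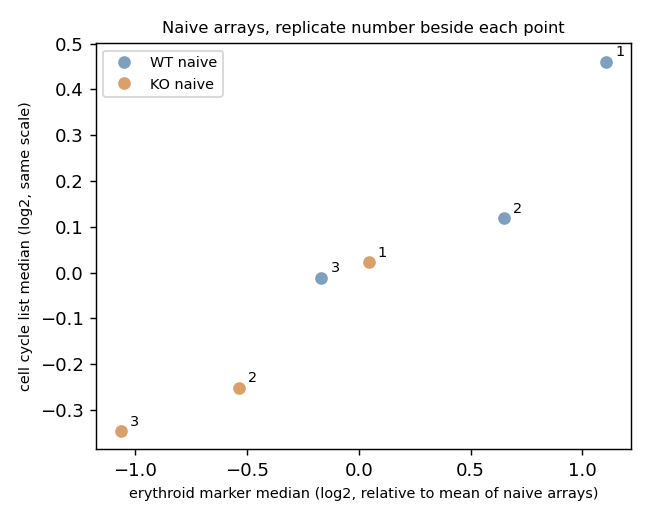
Median of the cell cycle list against the median of the erythroid markers in each of the 6 naive arrays, both in log2 relative to the mean of these arrays. Wild-type naive replicate 1 lies at 1.11 and 0.46, and knockout naive replicate 3 at -1.07 and -0.35.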

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

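All 3 tests of the cell cycle result were chosen only after that result was seen. In naive knockout cells the cell cycle list was lower by a median of -0.40, and its genotype difference was higher in activated than in naive cells by 0.41 (camera adjusted p = 5.2e-09; adjusted p = 0.904 with an estimated correlation), which is what singled it out as a difference between groups. Within genotype its median per array followed that of the erythroid markers (r = 0.936 over 6 naive arrays, exact one-sided permutation p = 0.0278, the smallest that 36 arrangements allow). Over the 6 arrays r was 0.970 (exact permutation p = 0.00417) and rho was 1 (exact permutation p = 0.00278), and r was 0.915 without the 2 farthest arrays. This was the 1 such relation computed, but the erythroid list was picked after results for all 29 lists were at hand. The permutation p-values take no account of that choice, and they show that the 2 medians moved together, not why. With the erythroid median as a covariate the genotype coefficient went from -0.38 (SE 0.18) to -0.0238 (SE 0.11). Erythroid precursors left in the naive preparations may therefore account for the difference. A lower T cell share that raised every other cell type alike would leave no B cell minus erythroid gap between genotypes, and this gap was 1.46 (SE 0.52). The gap restates list differences seen before the test was chosen, so it is no independent evidence. Its B cell part rests in part on knockout naive replicate 1 (0.66, against -0.22 and 0.18 in the other knockout naive arrays). An effect of cereblon loss on cell cycle transcripts in resting T cells cannot be told apart from erythroid precursors. The standard error of the adjusted coefficient leaves room for such an effect.

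The candidate cells are erythroid precursors, whose marker list had a median difference of -1.06 (camera adjusted p = 0.060). Its most abundant changing members were Car2, at 11.8, 10.6 and 9.53 in wild-type and 10.4, 8.64 and 8.14 in knockout naive arrays, and Car1, at 11.1, 10.3 and 9.73 against 9.83, 8.47 and 7.27, while Hba-a2 differed by 0.11 (limma adjusted p = 0.57). Negative magnetic bead selection, the sort used here, would remove such cells where the antibody mix holds an erythroid marker. Of the 7 list genes measured, 0 belonged to another of the fixed lists. In activated cells the list's median differed by -0.07 between genotypes, and Car2 and Car1 still stood at 8.35 and 7.20 in wild-type arrays. Which of the 7 genes T cells themselves express was not tested. Genes of other lists also ran along the naive arrays. Asns stood at 8.98, 7.92 and 6.73 in wild-type and 7.42, 6.28 and 5.71 in knockout naive arrays. Mpo stood at 8.34, 7.67 and 6.79 against 7.19, 7.14 and 5.96, although the median of its neutrophil list did not run this way. Other cells left in the preparations, or a difference shared by many genes of an array, therefore cannot be told apart from erythroid cells.

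The 18 genes besides Crbn past the threshold on the mean of both states, of which Mid1 and Rab4a by their brightest probe set and Nnt, Rell1 and Gpr83 by another passed in each state, held neighbours: Rell1 and 5830416I19Rik, Afp and Cxcl3, Erdr1 and Mid1, and Nnt and Tmem267. Afp and Cxcl3 differed by 0.04 and 0.03 in naive cells, so that pair rests on activated cells. Pairs within 10 measured genes of each other numbered 4, against a mean of 0.167 in 10000 random sets, of which 0% held as many. Among 100 splits of the arrays within state, 3, the real one included, held as many pairs, with 4 as the highest other. Of the 18 genes 0% lay among the 100 measured genes nearest to Crbn, which argues against a flanking segment of chromosome 6 within that window as their source. A longer segment was not tested, and Gprin3, among the 18, lies on chromosome 6 outside the window. Segments elsewhere in the genome that differ between the mouse colonies could therefore underlie part of these differences, and the substrains of the colonies are not given in the sources used here.

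The larger change on activation in knockout cells, in 71.4% of the genes called in both genotypes, was 59.4% without wild-type activated replicate 1, a value that leaves open how much of it rests on that array. Among 100 splits within state 15 gave a share as far from 50%, the others ranging from 19.0% to 75.0%, so the share may reflect chance differences between arrays.

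For the 27 genes of the naive genotype comparison and the 7851 of knockout activation, 10 splits are too few for a share under 0.05; in each, 1 split, the real one, reached the count, and the highest other gave 0. For the 19 genes of the mean of both states 1 of 100 splits, the real one, reached the count, and the highest other gave 12.

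A camera call on the interaction, a difference between groups, also singled out ribosome biogenesis genes (0.22, camera adjusted p = 5.2e-08), heat shock genes (0.21, 9.2e-04) and quiescence genes (-0.13, 0.010). None of these lists, nor the cell cycle list, passed with an estimated correlation (adjusted p = 0.904, and 0.927 for quiescence genes). That version called 0 lists in every comparison, so it cannot decide here. Ribosome biogenesis ran from 0.12 to 0.37 when 1 array was left out, and the quiescence call was lost in 3 such fits. Probe sets without a single gene symbol, which entered no comparison of genes, passed in limma in 17 cases in naive and 10 in activated cells. The largest of these differences was that of probe set 1439200_x_at, 3.47 in naive (limma adjusted p = 0.0021) and 3.00 in activated cells (limma adjusted p = 0.0090).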

How the results depend on the processing

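Leaving out both wild-type replicates numbered 1, and leaving out the wild-type naive replicates 1 and 2 of most erythroid signal, were chosen only after the results were seen. Among named genes past the threshold in the main fit or in the alternative, 0 reversed direction under any alternative. Changes of sign in genes that passed in neither were not counted. Crbn stayed past the threshold in naive cells under every alternative, from -1.18 to -0.99; in activated cells it ran from -1.03 to -0.78 when 1 array was left out and did not pass without moderation (-0.90, limma adjusted p = 0.285), with only the compared arrays (-0.90, limma adjusted p = 0.059) or without both replicates numbered 1 (-0.78, limma adjusted p = 0.165). The 27 naive genes became 55 with all probe sets counted, 15 among genes above the median level, 43 with a variance trend, 10 without moderation, 13 with only the compared arrays, 1237 with array weights (wild-type naive replicate 2 had a weight of 5.21), 277 (73 higher and 204 lower) with replicate number as a block, 6 with the fold threshold, 11 without both replicates numbered 1, 7 without the erythroid-high arrays, and 10 to 341 when 1 array was left out. The 11 activated genes became 22, 7 and 0 with all probe sets, the genes above the median level and no moderation, 2 with only the compared arrays, 3 with array weights, 5 with the fold threshold, 0 without both replicates numbered 1, and 1 to 28 when 1 array was left out; without a wild-type activated array the lone array left is assumed to vary like the other groups. The activation counts became 13208 and 14560 with all probe sets, where more features are counted, and 1694 and 2163 with the fold threshold; elsewhere they moved by less than 1.5 times, from 7475 to between 5554, without the erythroid-high arrays, and 7741 in wild-type and from 7851 to between 6731 and 8530 in knockout cells. The interaction count, 0, was 1 without moderation, 1 with the block, 11 (9 higher and 2 lower) with the block within genotype and 0 to 4 when 1 array was left out. The 19 genes of the mean of both states became 54 with all probe sets, 5 without moderation, 5 with the fold threshold, 8 without both replicates numbered 1, 12 without the erythroid-high arrays, and 9 to 20 when 1 array was left out. Ribosome biogenesis genes in activated cells reversed, to -0.046 both without wild-type activated replicate 1 and without both replicates numbered 1, against 0.23 without wild-type activated replicate 2. Apart from counts that change by construction, the cause was not tested. Residuals of same-numbered arrays correlated at 0.27, 0.087 and 0.22 between states in knockout cells, where each array correlated best with its own number, but at -0.30 and -0.18 in wild-type cells, and between the genotypes of naive cells at 0.39, 0.016 and 0.31. This is a hint from the data that some arrays of a number share more than the number, but it did not hold for every pair, and nothing in the labels pairs the arrays. In the wild-type activated group of 2 arrays the residuals mirror each other, so its values weigh little here. Mid1 followed the number in knockout cells (7.13, 7.77 and 8.36 in naive, 8.02, 8.75 and 9.34 in activated arrays). Erdr1 also kept the order of its knockout arrays (11.45, 12.74 and 12.52 in naive, 11.26, 12.59 and 12.37 in activated). So did probe set 1439200_x_at, while Rell1 did not. If same-numbered arrays share an animal, the p-values of the mean of both states may be too small, and leaving out 1 array would not leave out its animal. Array signal near background limits what can be seen of dim genes, and the number of arrays limits precision.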

Other observations

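The list of calcium entry and ion channel genes moved in both directions on activation: 4 of 13 rose and 6 fell in wild-type cells (camera adjusted p = 0.119), and 3 rose and 7 fell in knockout cells (camera adjusted p = 0.145). Among them Orai2 (-2.29 in wild-type and -2.56 in knockout cells), Itpr3 (-1.83 and -1.98), Itpr2 (-1.76 and -1.79) and Stim1 (-1.27 and -1.33) fell, each past the threshold in limma. Cereblon has been tied to ion channels in other cells, and between genotypes the list differed by 0.04 in naive (camera adjusted p = 0.989) and by -0.01 in activated cells (camera adjusted p = 0.835). The endoplasmic reticulum genes Sumf1 (-0.89 and -0.86) and Edem1 (-0.61 and -0.61), neighbours of Crbn on chromosome 6, fell on activation too, while Trnt1 rose by 0.95 and 1.51.

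The probe sets without a single gene symbol, 10092 in number with control probe sets set aside, were tested for activation too: 2042 passed in limma in wild-type and 2271 in knockout cells. The largest change was that of probe set 1446619_at, -4.20 and -4.32. On the interaction 1 passed, 1447122_at (0.87, limma adjusted p = 0.0469). Probe set 1439200_x_at stood at 6.97, 7.46 and 7.01 in wild-type naive, 9.84, 11.2 and 10.8 in knockout naive, 7.74 and 7.78 in wild-type activated and 9.84, 11.3 and 11.1 in knockout activated arrays.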
